A study of Drosophila melanogaster with 3 samples.

How the data were processed

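The libraries were prepared from whole mixed-sex prepupae of Drosophila melanogaster, aged 24 h, from 1 transgenic line that carries the gene Coop (CG1621) fused at its C-terminal end to eGFP, a green fluorescent protein used as a tag. Coop is known as a corepressor that binds Pangolin (Pan, the TCF factor of Wingless signalling). Chromatin was sheared by sonication to fragments of 200 to 800 bp, per the labels. There were 3 biological replicates, all of 1 group, and no second condition. The free-text description of each library names an input control, whereas the assay title, the antibody field and the notes deposited with each library describe a chromatin immunoprecipitation (ChIP-seq) library with a separate control. The libraries were therefore treated as ChIP libraries of the tagged protein, and every value depends on that reading.

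Per the deposited notes, the authors derived the list of each replicate from the alignment of that library and 1 control alignment shared by all 3 libraries, on the dm6 build, so errors of the control can recur in every list. The peak caller, its version and the threshold on the irreproducible discovery rate (IDR, a measure of agreement between replicates) were not given in the sources used here. The 5 lists comprised 1 relaxed list of 30000 regions per replicate, 1 relaxed list of 30000 regions from the pooled replicates, and 1 thresholded list of 6626 peaks. All 6626 thresholded peaks were the peaks of highest signal of the pooled list. They covered 6534 distinct intervals, because 92 entries repeated an interval with another summit. The deposited signal value of each peak is the score of the authors' peak caller, on a scale that differed between lists, and it was used to rank peaks within a list. The deposited −log10 q values were capped, at 4.19 for every thresholded peak, and were not used for ranking. Read counts were not analysed here, so the depth of each library is unknown, and intervals cover counting error of genes or sites only. For a list with no bound gene, the limit given is the upper exact 95% binomial limit.

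Coordinates are on dm6 and count from 1. Arm lengths of the reference genome (release 6) were compared with the lists, and every interval lay within its arm. Genes came from the Ensembl release 115 annotation, BDGP 6.54, with 13968 protein-coding genes and 19630 distinct transcription start sites (TSS) on arms 2L, 2R, 3L, 3R, 4, X and Y. A summit within 500 bp of a protein-coding TSS was called a promoter peak, and a gene with such a summit at any of its TSS was called bound. A thresholded peak was called found in a replicate when a summit among the 6626 regions of highest signal in that replicate lay within 100 bp of its own. Shares were also recomputed in the 6626 regions of highest signal of each replicate, which gave a mean and an SD over 3 replicates.

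Chance shares came from 1000 circular shifts of the summits within each arm, and from 100 shifts for annotation classes. The smallest two-sided p that 1000 shifts can give is 0.0020. Medians were compared with a two-sided permutation test of 100000 resamples. Gene groups were compared with two-sided Fisher's exact tests, and 23 gene lists were adjusted together by the Benjamini-Hochberg method, with all 13968 protein-coding genes as the background. Of 1121 names in the lists, 4 did not match a gene. A total of 24 consensus motifs and 2080 6-base words, each merged with its reverse complement, were searched in 201 bp centred on each summit and in 201 bp centred 500 bp away. Presence at the summit and in the downstream flank was compared with an exact McNemar test, adjusted over the motifs or the words, and the odds ratio is the ratio of windows with the sequence only at the summit to windows with it only in the flank. The printed flank share is the mean of both sides.

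Gene lists, motifs, tests and the rule for named genes were fixed before the data were examined. The rule took the 25 protein-coding genes nearest to the strongest thresholded peaks found in all 3 replicates, up to 4 bound members of highest signal per described list, all bound members of lists with 4 or fewer, Coop itself, and up to 10 motifs or words by odds ratio past an adjusted p of 0.05. The other motifs past that threshold, the Pan site, the chromosome 4 test and the genes of other RNA classes lie outside the rule and were chosen after values were seen. Results were recomputed under the changes that applied to each: the promoter window, the number of peaks or the assignment of peaks to genes for promoters and genes, the summit distance for overlap between lists, and the motif window or the control sequence for motifs and words. Only the overlap with the replicates and the mean shares over replicates were recomputed without each replicate. On simulated data, an odds ratio of 4 was recovered in 100% of 100 simulations for the list of 86 cytosolic ribosomal protein genes and in 86% for the list of 33 ecdysone regulators, and 0.429% of unchanged lists were called. These simulations drew each gene as bound independently, with 1 rate for all unchanged genes. They do not cover summits shared by neighbouring genes or rates that differ with the number of TSS. With displaced summits, 0 of 2080 words were called, a check that does not cover a difference in base composition between real summits and flanks. With 1 word planted in 5% of windows, that word ranked 1 by p. Moving 10% of 6626 displaced summits onto TSS raised the promoter share from 11.7% to 20.5%. The analysis used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.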

Results

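Binding of the eGFP-tagged Coop protein was mapped by ChIP-seq in 3 biological replicates of whole prepupae, with 6626 thresholded peaks from the replicates together. Read counts were not analysed here, so the depth of the libraries is unknown. No second condition was profiled, so the comparisons below set peaks against chance positions, flanking sequence or other genes. The peaks numbered 1186 on 2L, 1255 on 2R, 1428 on 3L, 1558 on 3R and 1191 on X, which is 48.6 to 50.8 peaks per Mb on these 5 arms. Chromosome 4, the small heterochromatin-rich chromosome, had 8 peaks, or 5.93 per Mb, and the Y chromosome had 0. None of the 5 deposited lists, relaxed lists included, held a region on Y, so its absence cannot be read as a lack of binding. Of 80 protein-coding genes on chromosome 4, 4 were bound (5%), against 21.2% of other genes (odds ratio 0.195, 95% CI 0.0714 to 0.534, Fisher's exact test p = 8.99e-05). On X, 21.6% of 2196 genes were bound, against 21.1% of 11749 genes on chromosomes 2, 3 and 4, a difference that Fisher's exact test did not separate from chance (odds ratio 1.03, 95% CI 0.924 to 1.15, p = 0.569). The call on X passed 0.05 with a 1000 bp window (odds ratio 1.11) and among peaks found in all 3 replicates (odds ratio 1.16).

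The first question was how far the replicates shared their peaks. The promoter of Cks30A, which encodes a cyclin-dependent kinase subunit, held the peak of highest signal in the thresholded list and in each of the 3 replicates, and the second strongest peak in each lay at NFAT, a transcription factor gene. Between the 6626 strongest regions of each replicate, 59.6% were shared by replicates 1 and 2, 55.5% by 1 and 3, and 68.4% by 2 and 3. Across all thresholded peaks, 3178 (48.0%) were found in all 3 replicates, against 0.000121% of shifted peaks on average (permutation p = 0.0020, the smallest the shifts can give). By replicate the share was 69.5% for replicate 1, 82.3% for replicate 2 and 78.1% for replicate 3, a mean of 76.7% ± 6.51 (SD, n = 3), with 0.998% to 1.01% by chance. Only 98 peaks (1.48%) were found in none of them. Signal across matched peaks was ranked most alike between replicates 2 and 3 (Spearman's rho 0.74 across 5793 peaks), and less alike between 1 and 2 (0.52) and between 1 and 3 (0.56). The thresholded list was the top of the pooled list by signal, and the pool was made from the same replicates. Its overlap with them therefore lies above chance by construction. Peaks are not independent replicates, and the shared control can add to the overlap.

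Summits lay at promoters of protein-coding genes more often than chance positions did. Promoters held 2683 summits (40.5%), against 11.5% of shifted summits (range 9.76% to 13.7%, permutation p = 0.0020, the smallest the shifts can give), a 3.52-fold excess. The excess was 5.36-fold with a 250 bp window, 2.45-fold with a 1000 bp window and 2.73-fold against summits displaced by 1 to 20 kb, of which 14.8% lay at promoters. In the replicate lists the share was 41.7% ± 6.19 (SD, n = 3), with 48.8% in replicate 1, 39.0% in replicate 2 and 37.3% in replicate 3. Coding sequence away from promoters held 1.15% of summits, against 13.9% after shifting, and 3′ untranslated regions held 0.740% against 4.51%. Introns held 38.1%, inside the range of the 100 shifts (37.2% to 41.7%), and intergenic sequence held 18.4%, below its range of 25.7% to 32.5%. Each summit had 1 class and promoters were assigned first, so the promoter excess alone lowers the other shares. Of the 3943 summits away from promoters, introns held 2524 and intergenic sequence 1221, against 39.5% and 29.9% of all shifted summits. Whether introns were enriched among summits away from promoters was not tested. The median signal of promoter peaks was 294, against 281 for other peaks (difference 12.6, permutation p = 0.0095), and this difference did not pass with a 250 bp window (6.91, permutation p = 0.181). It was 25.7 among the 3313 strongest peaks and 28.7 among peaks found in all 3 replicates.

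**Figure D1:**
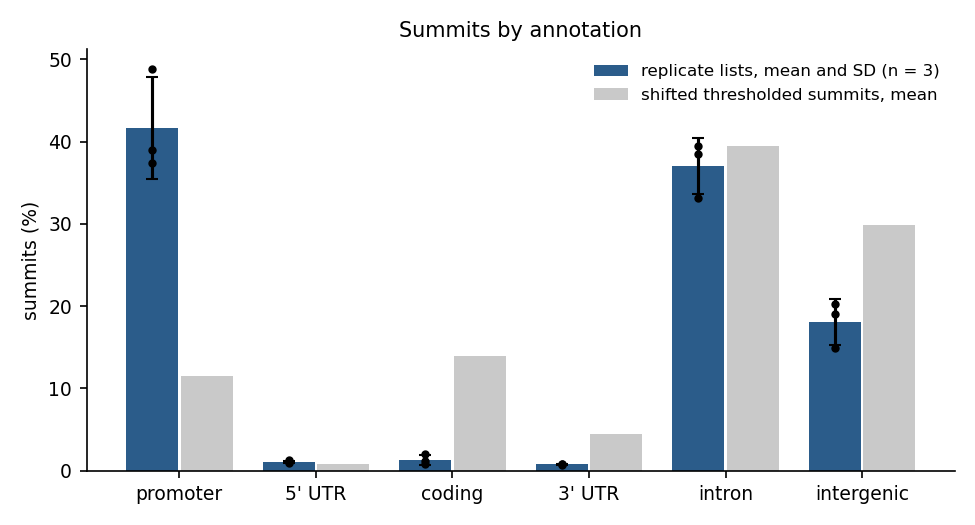
Share of summits in each annotation class (y axis, percent of summits), with blue bars for the mean over the 3 replicate lists with the SD, black points for each replicate, and grey bars for the mean of 100 circular shifts of the thresholded summits. Promoters held 41.7% of replicate summits against 11.5% after shifting, and coding sequence 1.32% against 13.9%.

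A total of 2953 protein-coding genes (21.1%) were bound, and 21.8% ± 3.93 (SD, n = 3) in the replicate lists. Cks30A (FBgn0010314, arm 2L, 9330763 to 9331981) had a summit at 9330704, 59 bp upstream of its TSS, with a signal of 8603. The summit at NFAT (FBgn0030505, X, 13624745 to 13664568) lay at 13642128, 47 bp upstream of an internal TSS, with a signal of 6585. Next by signal were COX7AL2, a cytochrome c oxidase subunit 7A-like gene (5534), the UDP-galactose transporter gene Ugalt (4819), CG14100 (4797), and Socs36E, a negative regulator of JAK/STAT signalling (4788). The apoptosis inducing factor gene AIF had 4633, CG4238 had 4455 and larp, which encodes an RNA-binding protein, had 3789. Coop itself followed at 3745. Peaks with signals from 3613 down to 3006 lay at CenG1A, PNPase (mitochondrial polynucleotide phosphorylase), Tasp1 (a threonine aspartase), Chro (the chromodomain protein Chromator), Oatp30B, l(2)k09022, dre4 (the Spt16 subunit of the histone chaperone FACT) and Men-b (a malic enzyme).
The remaining 7 of the 25 genes were CG13921 (2912), CG18549 (2906), Rab8, a vesicle-traffic GTPase (2857), Taf10b, a TFIID subunit (2759), CG1888 (2755), catalase Cat (2674) and the arginine methyltransferase gene Art3 (2654). All 25 summits lay within 463 bp of the TSS, and 13 of the 38 strongest peaks found in all 3 replicates lay at no promoter.

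Genes with divergent promoters, meaning a TSS on the other strand within 1000 bp upstream, were bound more often than the rest. Of 5052 such genes 1564 were bound (31.0%), against 1389 of 8916 others (15.6%, odds ratio 2.43, 95% CI 2.24 to 2.64, Fisher's exact test p = 2.4e-98). A summit between close promoters counts for both genes, so the genes are not independent and the test can overstate the difference. The comparison was not repeated with each summit given to the nearest TSS alone.

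Of 23 gene lists, 5 were bound more often and 4 less often than other genes. Cytosolic ribosomal protein genes stood highest, at 63 of 86 (73.3%, exact 95% CI 62.6% to 82.2%) against 20.8% of the rest (odds ratio 10.4, Fisher's exact test, adjusted p = 1.01e-23). The strongest of their peaks lay at RpL7 (signal 1368), RpS27 (782), RpS4 (715) and RpL23A (671). The share of these genes bound differed between replicates, with 80.2% in replicate 1, 64.0% in replicate 2 and 51.2% in replicate 3, or 65.1% ± 14.6 (SD, n = 3). The share of all protein-coding genes bound had the same order, with 25.9%, 21.3% and 18.1%. The RpS27 peak was not found in all 3 replicates. Among peaks found in all 3 replicates the odds ratio was 5.83, still past the threshold. Other lists tied to translation and energy did not pass with the 500 bp window. Mitochondrial ribosomal protein genes were bound at 19 of 73 (odds ratio 1.31, exact adjusted p = 0.402), with peaks at mRpS23 (3613), mRpS10 (2654), mRpL41 (2276) and mRpL23 (1808). The first 2 of these share their summits with CenG1A and Art3, and with each summit given to the nearest TSS alone the odds ratio of the list was 0.434, which did not pass either. Translation factor genes were bound at 18 of 53 (1.92, exact adjusted p = 0.0584), including eIF6 (2097) and eIF4EHP (1363), and passed with a 250 bp window (odds ratio 2.38). Oxidative phosphorylation genes were bound at 16 of 77 (0.978, exact adjusted p = 1.00), including ND-ASHI (1480, list odds ratios 0.336 to 1.23 in the other settings), and proteasome genes at 7 of 48 (0.636, exact adjusted p = 0.431), including Rpn3 (418, list odds ratios 0.157 to 0.807 in the other settings).

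Regulators of the response to ecdysone, the steroid hormone that triggers metamorphosis, were bound at 18 of 33 (54.5%, exact 95% CI 36.4% to 71.9%, odds ratio 4.50, Fisher's exact test, adjusted p = 0.000118). Their strongest peaks lay at dre4 (3030), the caspase gene Dronc (2120), the transcription factor gene Eip93F (1153) and ImpL2 (1003), and 49.5% ± 1.75 (SD, n = 3) of the list was bound in the replicate lists. With gene length, number of TSS, divergence and density in a logistic model, the odds ratio was 2.41 and did not pass. It was 2.78 among the 3313 strongest peaks and 2.52 with genes stratified by number of TSS, both past the threshold. Heat shock and chaperone genes were bound at 13 of 23 (56.5%, odds ratio 4.87, exact adjusted p = 0.000832), with Hsp27 (2645), Hsp83 (748), CG11267 (450) and Hsc70-5 (446) the strongest, and 50.7% ± 13.3 (SD, n = 3) in the replicate lists. Among the 3313 strongest peaks this list did not pass (odds ratio 2.61).

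The tagged protein is known as a corepressor of Wingless targets, and both Wingless lists were examined. Components of the Wnt pathway were bound at 12 of 29 (41.4%, odds ratio 2.64, 95% CI 1.26 to 5.53, Fisher's exact test, adjusted p = 0.0303). The kinase gene sgg had a signal of 1745, the corepressor genes gro and CtBP had 1179 and 906, and CkIalpha had 496. The share was 41.4% in each of the 3 replicate lists. The call ended among the 3313 strongest peaks (odds ratio 1.93), with 1 gene per shared promoter (1.80), with genes stratified by number of TSS (1.90) and in the logistic model (1.35). Wingless target genes were bound at 12 of 31 (38.7%, odds ratio 2.36, exact adjusted p = 0.0581), which did not pass, with peaks at Dtg (619), ct (451), fz3 (426) and Dll (340). This list passed with a 250 bp window (odds ratio 2.92), among peaks found in all 3 replicates (2.91) and with the nearest TSS alone (3.08). Genes of the Notch pathway and the E(spl) complex were bound at 14 of 27 (51.9%, odds ratio 4.03, exact adjusted p = 0.00136), including gro, numb (733), E(spl)m7-HLH (465) and E(spl)mdelta-HLH (356). That call ended with a 250 bp window (2.31), among peaks found in all 3 replicates (2.38) and with 1 gene per shared promoter (2.91). The E(spl)m7-HLH and E(spl)mdelta-HLH peaks were found in replicates 2 and 3 and not in replicate 1.

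Chemoreceptor, cuticle, glue and histone genes were the 4 lists bound less often than other genes. Chemoreceptor genes were bound at 1 of 180 (0.556%, odds ratio 0.0205, Fisher's exact test, adjusted p = 1.89e-16), the carbon dioxide receptor gene Gr63a (signal 178), with odds ratios of 0.0132 to 0.0334 in the other settings. Cuticle protein genes were bound at 3 of 122 (2.46%, odds ratio 0.0931, exact adjusted p = 1.27e-08), namely Cpr97Ea (467), Lcp9 (244) and Cpr72Ea (241), with odds ratios of 0.0605 to 0.199 in the other settings. None of 22 salivary glue genes was bound, which allows a share of up to 15.4% (exact adjusted p = 0.0227, past 0.05 in 3 of 8 settings including this one), and none of 111 replication-dependent histone genes, which allows up to 3.27% (exact adjusted p = 3.80e-11). The histone genes lie in near-identical tandem copies, so unique mapping of short reads and the share itself are uncertain. Each copy counted as a separate gene, so this p and the limit of 3.27% can overstate the evidence. Muscle structural genes were bound at 3 of 27 (sls, Zasp52 and Tm1, exact adjusted p = 0.331) and neuronal genes at 3 of 25 (elav, Rbp9 and Csp, exact adjusted p = 0.404). Hemocyte genes were bound at 2 of 16 (drpr and crq, exact adjusted p = 0.600) and Hox genes at 1 of 8 (abd-A, exact adjusted p = 1.00), and none of these 4 lists passed. With genes stratified by number of TSS and in the logistic model, muscle genes (odds ratios 0.225 and 0.175) and neuronal genes (0.222 and 0.110) passed as bound less often. In the other settings the odds ratios of Hox genes ran from 0.182 to 0.694 and those of hemocyte genes from 0.223 to 1.01, none past the threshold. Of the genes named in this paragraph, only Cpr97Ea, sls and elav had their strongest promoter peak found in all 3 replicates.

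Lists of chromatin regulators had some strong peaks. Corepressor and histone deacetylase genes were bound at 8 of 18 (odds ratio 2.99, Fisher's exact test, adjusted p = 0.0642), including Coop itself, Gug (1412), gro and CtBP, and 61.1% ± 5.56 (SD, n = 3) of the list was bound in the replicate lists. Genes with BESS or MADF domains, the family of Coop, were also bound at 8 of 18 (exact adjusted p = 0.0642), with brwl (1454), hng3 (1201) and CG11723 (885) after Coop, and 48.1% ± 8.49 (SD, n = 3) in the replicate lists. Both lists passed in 4 other settings: the 1000 bp window (odds ratios 6.05 and 4.76), the 3313 strongest peaks (4.71 for each), peaks found in all 3 replicates (5.32 for each) and the nearest TSS alone (3.10 for each). The BESS and MADF list also passed with 1 gene per shared promoter (6.997). Coop counted among the 8 bound genes of each list, and neither list was recomputed without it. Binding at Coop itself cannot be told apart from an effect of the transgene, as set out below. The corepressor list had odds ratios of 1.25 with 1 gene per shared promoter, 1.78 with genes stratified by number of TSS and 1.18 in the logistic model, and did not pass in these. Polycomb and Trithorax group genes were bound at 8 of 25 (exact adjusted p = 0.311), with ph-p (2536), brm (969), ph-d (696) and Trl (532). DNA replication genes were bound at 13 of 41 (exact adjusted p = 0.188), including Dp (723), dpa (472), Orc1 (400) and E2f1 (359), and fat body genes at 8 of 19 (exact adjusted p = 0.0701), including Cat, Mtp (442), Ilp6 (297) and bmm (271). The fat body list passed in the logistic model (odds ratio 3.26), and had 1.23 with a 250 bp window, 1.39 among the 3313 strongest peaks and 1.56 among peaks found in all 3 replicates. The peaks at E2f1 and Mtp were not found in all 3 replicates.

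**Figure D2:**
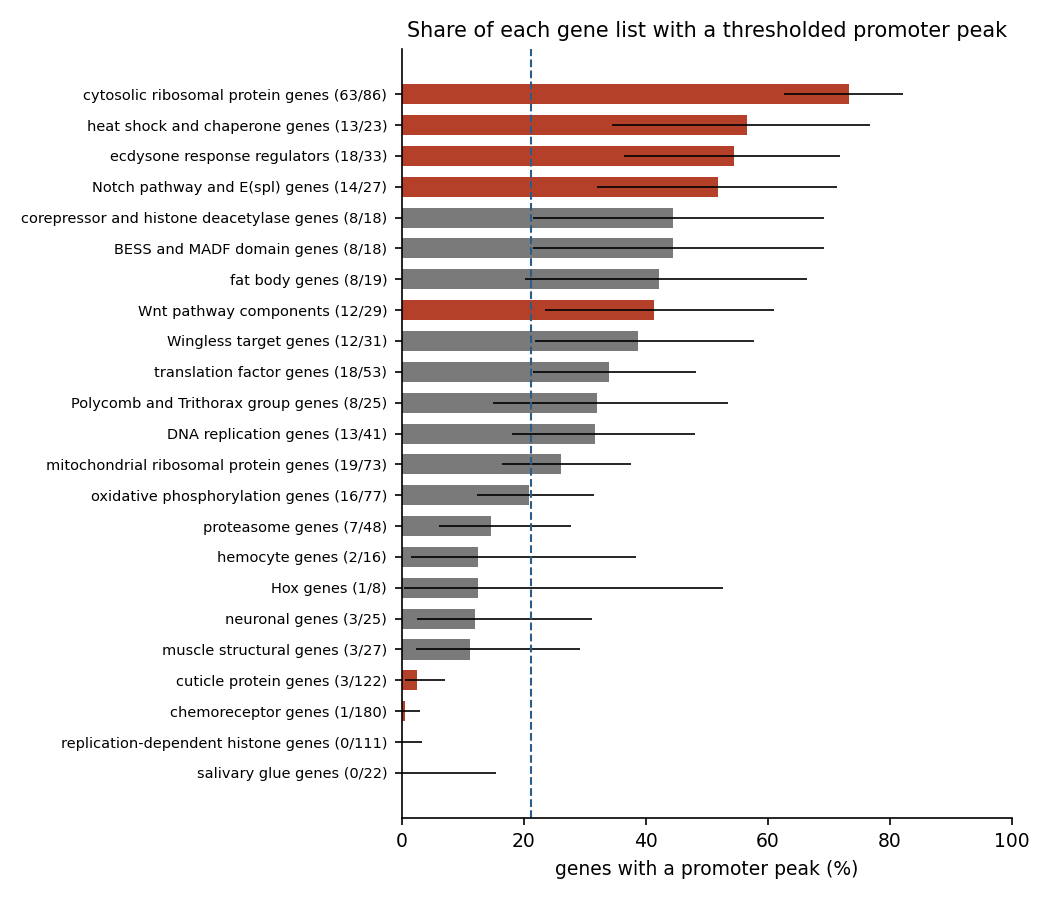
Share of each of the 23 gene lists with a promoter peak (x axis, percent of genes), with bound and total genes in parentheses, lines for exact 95% binomial intervals, red for an adjusted p under 0.05, and a dashed line for all protein-coding genes (21.1%). Cytosolic ribosomal protein genes stood highest at 73.3%.

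Of 24 motifs, 7 were more frequent and 5 less frequent at summits than in flanks of the same peaks. Base composition was not matched between summits and flanks, so differences for GC-rich or A-rich sequences cannot be told apart from composition. Motif 1 (GGTCACACT), bound by the promoter factor M1BP, was present at 1.69% of summits and 0.272% of flanks (odds ratio 5.09, exact McNemar test, adjusted p = 2.45e-14). The DRE (TATCGATA), bound by Dref, was present at 2.20% and 0.687% (odds ratio 3.37, exact adjusted p = 4.78e-13). Next were the Su(Hw) core, the site of an insulator protein, at 1.06% and 0.460% (2.92), the GAGA repeat bound by Trl at 6.93% and 4.25% (1.78), Ohler motif 7 at 4.74% and 3.09% (1.69), Ohler motif 6 at 9.81% and 6.99% (1.48), and the poly-A tract at 14.2% and 12.5% (1.15). These 7 motifs were higher at the summits in 3 of 3 replicates, with 2.49% ± 1.38 at summits for the DRE against 0.833% ± 0.115 in flanks (SD, n = 3). GAGA repeats were not centred on the summits. In 25 bp bins at promoter peaks they numbered 22.0 and 20.5 per 1000 peaks at −112.5 and 137.5 bp, against 11.2 and 10.1 at −12.5 and 12.5 bp. At other peaks the values for these bins were 16.2 and 15.7, against 9.13 and 11.7. Lower at summits were the ftz-f1 site (odds ratio 0.515), the Pho site (0.782), the Mad GC-rich site (0.788), the Adf1 repeat (0.822) and the Pan helper site (0.824), the Mad and Adf1 sites in 2 of 3 replicates. The Mad site was higher with the wider window (1.10) and the Adf1 repeat was higher at promoter peaks than at unbound promoters (1.31), both past the threshold, so neither had 1 direction. The call for the Pan helper site ended in 5 settings, where its odds ratio ran from 0.780 to 1.05. The ftz-f1 call ended at other peaks (0.625) and against unbound promoters (0.735), and among the 3313 strongest peaks the odds ratio was 0.289. The site of Pan, the known partner of Coop, was present at 5.90% of summits and 6.03% of flanks (odds ratio 0.992, exact McNemar test, adjusted p = 1.00). In the replicate lists the Pan site stood at 5.94% ± 0.0982 and 5.95% ± 0.0377 (SD, n = 3). The other 11 motifs did not pass, among them the core promoter motifs TATA box (odds ratio 1.15) and Ohler motif 8 (1.29).

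The DRE, Motif 1 and Ohler motif 7 were higher at promoter peaks alone, with odds ratios of 4.55, 7.21 and 2.75. At the 3943 other peaks these 3 motifs did not pass (0.929, 1.38 and 0.991), and the difference between both classes of peaks was not tested. Compared with promoters of genes that had no peak within 1000 bp, promoter peaks differed for 8 of 24 motifs, 5 higher and 3 lower. Among these were the GAGA repeat (9.06% against 3.32%, odds ratio 2.90, Fisher's exact test, adjusted p = 2.66e-17), Motif 1 (3.76% against 2.24%, 1.71) and Ohler motif 7 (7.53% against 5.18%, 1.49). The DRE did not differ there (4.96% against 4.25%, odds ratio 1.18, exact adjusted p = 0.413), nor did the Su(Hw) core (1.76), Ohler motif 6 (1.204) or the poly-A tract (1.01). Motif 1 had odds ratios of 1.38 to 9.17 and the Su(Hw) core of 1.51 to 3.54 over all other settings. The poly-A call also ended with the wider window (1.02) and at promoter peaks alone (1.08), as did the Su(Hw) call at promoter peaks alone (2.10).

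**Figure D3:**
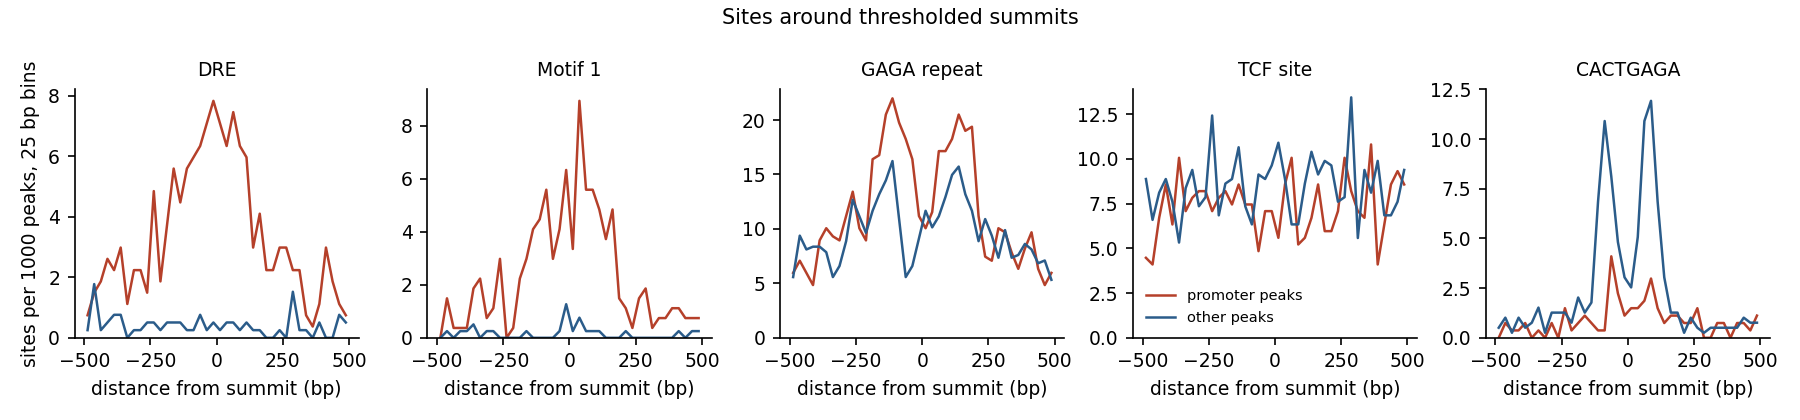
Sites per 1000 peaks in 25 bp bins (y axis, scale differs between panels) by distance from the summit in bp (x axis), for promoter peaks (red) and other peaks (blue). DRE and Motif 1 sites peak near the summits of promoter peaks, and the TCF site of Pan shows no peak at the summit. GAGA repeats are most frequent to either side of the summit, and CACTGAGA peaks on both sides of the summit at other peaks.

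Of 2080 6-base words, 339 were more frequent and 416 less frequent at summits than in flanks. The limit on base composition given for the motifs holds for the words too. The leading words overlapped each other. ACACTG was present at 17.1% of summits and 7.85% of flanks (odds ratio 2.41, exact McNemar test, adjusted p = 1.20e-54), and the next by odds ratio were ACAGTG (2.25), CAGTGC (2.07), CACTGA (2.03), AGTGTA (2.00), ACTGAG (1.96), GTGCAC (1.95), CGATAG (1.86), CCGTAC (1.86) and GAGAGA (1.72). All 10 were higher at summits in 3 of 3 replicates, with 16.7% ± 1.46 at summits and 7.89% ± 0.310 in flanks for ACACTG (SD, n = 3). CGATAG, which shares CGATA with the DRE, was higher at promoter peaks (odds ratio 2.58) and did not pass at other peaks (1.12). AGTGTA and GTGCAC did not pass at promoter peaks (1.22 and 1.198) and were higher at other peaks (2.52 and 2.58). Differences between both classes of peaks were not tested. Against unbound promoters ACTGAG (1.27) and AGTGTA (0.995) did not pass.

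The tagged gene lay in a dense group of peaks. Coop (2R, 7490836 to 7492589, minus strand) had 8 thresholded summits within 5000 bp, and the replicate lists had 7.33 ± 0.577 (SD, n = 3) among their 6626 strongest regions. The strongest summit, at 7492423, lay 111 bp upstream of a Coop TSS, within the annotated gene, and ranked 11 in the thresholded list and 12, 53 and 10 in replicates 1, 2 and 3. The other summits were at 7490695 and 7490899 near the 3′ end of Coop, at 7492635 and 7493348 upstream of it, at 7488836 inside wech, at 7489888 between wech and Coop, and at 7496298 inside CG1620. Their ranks ran from 285 to 4664. The labels call the line transgenic for tagged Coop and do not say whether it has a further copy of the locus, whose reads would map to the same place.

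**Figure D4:**
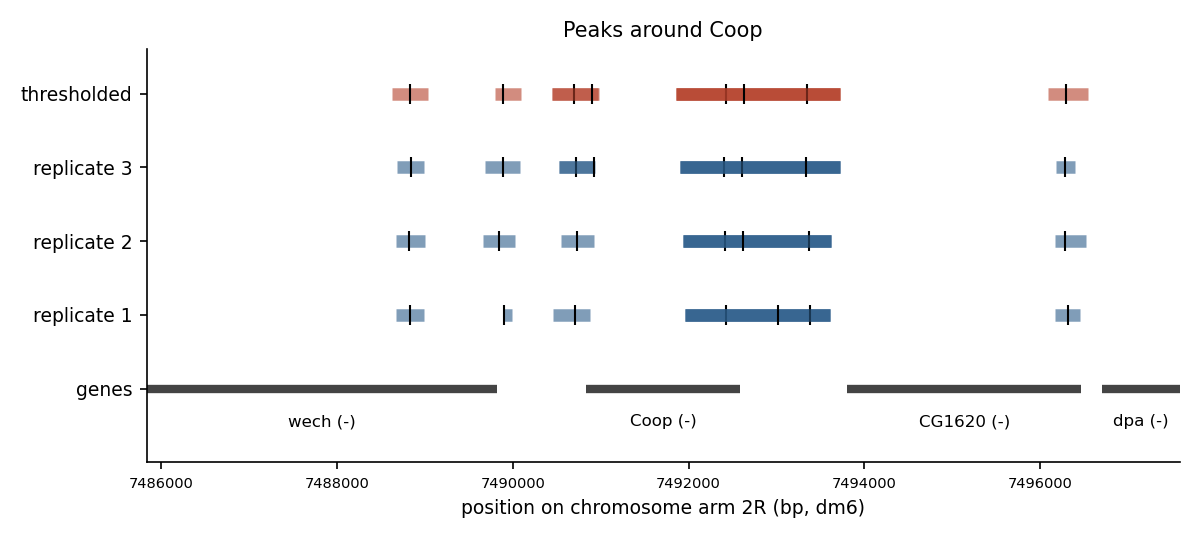
Peaks around Coop on arm 2R (x axis, dm6 position in bp) in the thresholded list (red) and among the 6626 strongest regions of each replicate (blue), with bars for peak intervals, ticks for summits and grey bars for genes with their strand. Of the 8 thresholded summits, 6 were found in all 3 replicates.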

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

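Displacement by 1 to 20 kb, stratification, the logistic model, splits by peak class and the alternatives for chromosome 4, tRNA genes and the tagged gene were chosen after seeing the data. The shares of peaks found in all replicates (25.1% to 79.2%) and at promoters (33.8% to 49.7%), and the divergent promoter odds ratio (1.80 to 2.55), kept their direction and their side of the threshold in every alternative run. For divergent promoters these runs changed the promoter window or the set of peaks, not the assignment of summits to genes. Leaving out 1 replicate gave 54.6% to 66.5% for peaks found in the others, and 38.2% to 43.9% for the mean promoter share. With a 250 bp window the signal difference was 6.91 and not past the threshold, and the X odds ratio turned to 0.966. The X odds ratio passed at 1.11 (1000 bp) and 1.16 (peaks found in all replicates). The number of gene lists called ran from 7 to 12, against 9. Lists whose odds ratio turned were not past the threshold on either side: oxidative phosphorylation at 1.12 (250 bp), 1.23 (1 gene per shared promoter) and 1.08 (logistic model), hemocyte at 1.01 (1000 bp), mitochondrial ribosomal proteins at 0.434 (nearest TSS) and 0.484 (1 gene per shared promoter), and Polycomb and Trithorax at 0.961 (logistic model). The number of motifs called was 6 at other peaks alone, against 12, where the DRE turned to 0.929 and Ohler motif 7 to 0.991. The Pan site gave 1.03 with both a narrower and a wider window, 1.05 at other peaks and 1.18 against unbound promoters, and did not pass in any of these. With the wider window the Mad GC-rich site turned to 1.10, past the threshold, and the Adf1 repeat to 1.08. Against unbound promoters the Adf1 repeat turned to 1.31, past the threshold, the Mad site to 1.06, the Pan helper site to 1.05 and the word AGTGTA to 0.995, with 498 words called, against 755. The cause was not tested for these. Of 182 list odds ratios under other settings, 143 kept direction and side of the threshold, 18 newly passed and 14 no longer passed; for motifs 64 of 91 and for words 55 of 60 kept both. Of 91 named genes, 76 had a promoter peak within 250 bp, 91 within 1000 bp, 78 among the 3313 strongest peaks and 72 among peaks found in all replicates. No paired analysis was possible because there was 1 group. Coop had 7 peaks among the strongest 3313 and 6 among those found in all replicates, against 8. Depth is unknown, so what it limits cannot be stated.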

Other observations

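Genes of other RNA classes, examined after the data were seen, were bound less often than protein-coding genes. A summit lay within 500 bp of the 5′ end of 18 of 290 tRNA genes (6.21%, odds ratio 0.247), 14 of 269 snoRNA genes (5.20%, odds ratio 0.205), 2 of 32 snRNA genes (6.25%, odds ratio 0.249) and 307 of 3289 ncRNA genes (9.33%, odds ratio 0.384), against 21.1% of protein-coding genes. Fisher's exact test gave adjusted p of 7.38e-12, 1.39e-12, 0.0477 and 3.69e-61 in that order. The tRNA odds ratio was 0.131 with a 250 bp window, 0.441 with a 1000 bp window, 0.375 among the 3313 strongest peaks and 0.391 among peaks found in all 3 replicates, each past the threshold. None of 99 rRNA genes had a summit, but these are repeated copies, so unique mapping of reads is uncertain. Mapping was not checked for tRNA genes, which also occur in similar copies. Each gene of these RNA classes counted at its 5′ end alone, and a protein-coding gene at any of its TSS. The 8-base word CACTGAGA, chosen after the data were seen, was present at 5.15% of the 3943 summits away from promoters and 0.533% of their flanks, and at 4.71% ± 0.963 and 0.588% ± 0.0778 in the replicate lists (SD, n = 3). At promoter peaks it was present at 1.53% of summits and 0.447% of flanks (windows with it only at the summit against only in the flank 3.42 to 1, 95% CI 1.76 to 7.14). Of 216 sites, 198 (91.7%) had the summit downstream on the strand that reads CACTGAGA, at a median of 65.5 bp (quartiles 47.3 and 80.5 bp, two-sided exact binomial p = 1.65e-39). The 216 sites lay in 203 windows, and 146 of them had a base masked in the reference, taken below as repeated sequence. Sites in 1 window or in copies of 1 repeat are not independent, so this p can overstate the evidence.

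All tests of the patterns weighed here were chosen after the patterns had been seen. The tests of tRNA genes, of the model with gene length, of masked sequence and of dense promoters were set before their own results were seen, and the tests of widely transcribed promoters, of a chance word, of repeats as the only source and of extra transgene copies only after their results, or values that bear on them, had been seen. No biological explanation was tested, since there was 1 group. For the first pattern, the binding of cytosolic ribosomal protein promoters, if any widely transcribed promoter gave signal, oxidative phosphorylation and proteasome genes together would stand near an odds ratio of 10.4, and they stood at 0.840 (95% CI 0.533 to 1.32). Both lists were picked after their values were seen, and heat shock and chaperone genes (odds ratio 4.87) and translation factor genes (1.92, not past the threshold) stood higher, so signal at some widely transcribed promoters is not excluded. A raised share was not seen at tRNA genes, the polymerase III genes tested, with an odds ratio of 0.247 (95% CI 0.153 to 0.398), and at most 0.441 in other settings. This test is weak, because each tRNA gene counted at 1 end and unique mapping of reads to these genes was not checked. In a model with gene length, number of TSS, divergence and density the odds ratio of ribosomal protein genes was 12.2 (95% CI 7.41 to 20.1). Transcript levels and open chromatin were not analysed here, so signal at the most strongly transcribed genes alone stays open, and a specific association of Coop with these promoters is a hypothesis.

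The second pattern, the word CACTGAGA at summits away from promoters, ranked 1 among 8-base words on arms 2L and 2R alone. On the other arms, windows with it only at the summit outnumbered those with it only in the flank by 12.9 to 1 (95% CI 6.79 to 27.5). Those arms were not held out, since they had entered the search for CACTGA and ACTGAG, which this word contains. A chance pick was therefore not tested independently. Repeated sequence is a candidate explanation, since 67.6% of the 216 sites (95% CI 60.9% to 73.8%) had a masked base or lay in an annotated mobile element, against 31.6% of 3880 sites outside the peaks by the same definition. None of the 216 lay in an annotated mobile element, and the program that masked the reference is not stated, so masked bases were only taken to be repeats. Masked sequence was not the only source, because unmasked sites alone gave a ratio of 4.71 (95% CI 2.62 to 9.09). Whether another DNA-binding factor or the repeats themselves give the signal there was not tested, nor was whether the tagged protein is at these sites at all.

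The third pattern is the group of peaks at Coop. Of 3785 other genes with at least 7 TSS within 5 kb, 1.72% had as many as 8 peaks (95% CI 1.33% to 2.18%), above the 1% set in advance for excluding dense promoters. Among the 1378 of them no longer than Coop, a limit that was not part of the planned test, 0 had as many. Weak regions outside thresholded peaks within 10 kb were more numerous at Coop than at 81.7% of 100 genes with strong promoter peaks on average (82.0%, 86.0% and 77.0% in replicates 1, 2 and 3), which leaves extra copies of the locus open. Binding of Coop at its own gene, dense promoters and the transgene cannot be told apart, because the lists hold no reads and the labels no copy number.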
